A study of Mus musculus with 4 samples.

How the data were processed

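CD45+ cells of MOC2 tumours were profiled as single cells with 10x Chromium 3' chemistry (v2 or v3 per the labels). Per the labels, about 6000 cells per sample were captured from 150000 sorted live cells. Per the submitters' processing notes, Cell Ranger 2.1.1 and the build mm10 were used; the role of each, the aligner and the annotation release are not given in the sources used here. The deposited matrices hold raw UMI counts per gene and barcode, not normalized and not filtered, with 32285 genes and 6794880 barcodes each. Matrices of control replicate 2, K17KO replicate 1 and K17KO replicate 2 were used; control replicate 1 was not used here. Gene positions came from the GENCODE annotation of mm10, in which 127 of the 32285 features had no position.

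Cells were barcodes with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs. Scrublet, with an expected doublet rate of 5%, called 6 of 13983 cells (0.043%), a share too low for a working caller, so doublets remain; 13977 cells were kept. Cells were scaled to 10000 UMIs and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0 gave 27 clusters, with no integration of libraries. Clusters were named from markers of 19 classes fixed before the data were examined, where at least 3 markers of a class were raised. A cluster with enough markers still stayed unnamed if its first leading gene marked another class or its leading genes held more markers of another class. The same applied to a low UMI count with no own marker among the leading genes. A rule that left low-UMI clusters led by mitochondrial genes unnamed was set after the data were seen. Unnamed clusters hold 7.96% of the control cells, 13.6% of K17KO replicate 1 and 24.8% of K17KO replicate 2. Cluster names were rebuilt here and are not the authors'. The control had fewer genes per cell (median 1488) than the K17KO libraries (1966 and 1957), but class shares differ, so this need not hold within a class. Within neutrophils, 3455 control cells held 17476000 UMIs against 4476600 in 1137 cells and 3030900 in 712 cells, so the control cells were the deeper. The same held for monocytes and macrophages (20190000 UMIs in 1190 cells against 10125000 in 1002 and 10331000 in 867). In T cells the control lay between the K17KO libraries.

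Shares of called cells carry exact binomial intervals and single-library UMI levels exact Poisson intervals (95%). These intervals, and the floor of 3 counts used for a count of 0, cover counting error only. For each class with at least 50 cells in every library, raw UMI counts were summed per library and tested with edgeR's quasi-likelihood test (filterByExpr, TMM, robust), with Benjamini-Hochberg adjustment and a threshold of 0.05. This gave 6 fits, all cells included; B cells had too few cells and were not tested. CPM are UMI counts scaled to the total of the summed cells. Cell counts per class were tested with edgeR with total cells as library size. All tests were two-sided. SE is the fold change divided by the root of the F statistic. The design has 1 residual degree of freedom, so most of the spread of a gene is borrowed from the other genes. Free RNA shares per class were computed as the level of a marker gene of other cells in the class over its level in droplets of 1 to 100 UMIs. They are upper limits, since joined cells and the class itself can bring the same transcripts.

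Lists of genes, 16 in all, were fixed before the data were examined and tested with camera (correlation preset to 0.01), adjusted over lists within a class; a correlation estimated from the residuals and fry were run beside it. None of the 50 list calls held with an estimated correlation or with fry. Named genes followed a rule fixed before the data were examined. It took Krt17, genes with the largest fold change past the threshold outside the lists (up to 6 per direction, or 3 in dendritic and NK cells) with a mean CPM of at least 50, up to 3 members of each list with the smallest p, and Cxcl9, Cxcl10, Cd274, Cd8a, Cd4, Foxp3, Ifng, Pdcd1 and Arg1. The keratins other than Krt17, Xist, Ddx3y, Mgp and the genes of cluster descriptions were named after their values were seen.

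The test was tested on simulated data with 200 genes changed among 9436 (neutrophils) to 15117 (all cells) genes. Of genes changed by 1 (log2), it recovered 39.0% in all cells, 32.0% in NK cells, 16.3% in T cells, 16.7% in dendritic cells, 45.3% in monocytes and macrophages and 37.2% in neutrophils. Of genes changed by 2 (log2), it recovered 82.8%, 88.4%, 79.0%, 71.6%, 91.9% and 89.6% in the same order, and false calls were 1.18% to 6.20% of calls. Small changes are therefore often missed. In the simulation the control varied like the K17KO libraries, at the dispersion fitted to the data, and only 200 genes changed. It therefore cannot show how many calls are false if the lone control varies in another way.

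Alternatives were other limits on UMIs and mitochondrial share, other cell calling (OrdMag: the 99th percentile of UMIs divided by 10), doublet handling, clustering resolution 0.5 and 2.0, other scalings, gene filters, a fit without the robust option, DESeq2, thinning of cells to 1000 UMIs and leaving out each K17KO library. Removing the 5% of cells with the highest doublet scores and leaving out unnamed cells were chosen after seeing the data. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, scanpy 1.11.5, leidenalg 0.10.2, scipy 1.17.1, scikit-learn 1.9.0, pandas 2.3.3, numpy 2.4.6 and Python 3.11.15.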

Results

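Transcripts of single CD45+ immune cells were counted in tumours that MOC2 cells, a mouse head and neck cancer line, formed in C57BL/6 mice. The tumours grew either from parental cells (control) or from cells in which Krt17, the gene of the stress keratin K17, had been targeted by CRISPR (K17KO). Of the 4 samples, 2 per group, control replicate 1 was not analysed here, which left 1 control library and 2 K17KO libraries. The libraries held 58243788 UMIs (control replicate 2), 38858769 UMIs (K17KO replicate 1) and 41861061 UMIs (K17KO replicate 2). After filtering, 5842, 4305 and 3830 cells remained, with medians of 4947, 5697 and 5653.5 UMIs per cell. The comparison asks how the immune cells of the tumour differ when K17 is lost. Every test set 1 library against 2, so the spread came from the 2 K17KO libraries with 1 residual degree of freedom, and the lone control was assumed to vary in the same way. The labels speak of duplicate tumours without saying whether these came from separate mice, so edgeR p-values cover no more than the spread between these libraries. Most of that spread is borrowed from other genes. Camera p-values set the genes of a list against other genes at a preset correlation, so they do not measure the spread between libraries.

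Krt17 (ENSMUSG00000035557, chromosome 11, 100256217 to 100261029, minus strand, mm10) was seen in the control library and in neither K17KO library. Summed over all called cells it had 45 UMIs in control replicate 2 (0.899 CPM, counts scaled to the library total, 95% exact Poisson interval 0.656 to 1.20) and 0 UMIs in each K17KO library. Against a floor of 3 UMIs per library, the level was at least 10.1-fold lower in K17KO replicate 1 and at least 9.98-fold lower in K17KO replicate 2 (adjusted p = 0.0313, edgeR). Over the alternatives the adjusted p of Krt17 in all cells ran from 0.0129 to 0.178; the highest came without a gene filter, and DESeq2 gave none. Among tumour-like cells, a small group led by Cdkn2a and Hmga2 with the epithelial keratins Krt8 and Krt18, the control library held 23 Krt17 UMIs in 33 cells. At a minimum of 1000 UMIs and with OrdMag cell calling the cluster that best matched this class stayed unnamed. The K17KO libraries held 0 in 25 cells and 0 in 71 cells, of which only 8 and 28 had at least 20000 UMIs. Only 4 of the 33 control cells had a Krt17 UMI, and 1 cell held 17 of the 23, so the intervals cover counting error only and the check of the labels is weak. Where in the gene the CRISPR edit lies is not given in the sources used here.

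Other epithelial keratins differed in the same cells. Krt14, a keratin of basal epithelium, had 48 UMIs in control tumour-like cells in 11 of 33 cells, and 0 in both K17KO libraries. Krt15 also had 48 and 0, but in only 3 control cells, with 23 UMIs in 1 of them. Krt19 (chromosome 11, 100140810 to 100148665) stood at 1567 CPM in the control against 138 in K17KO replicate 1 and 79.3 in K17KO replicate 2. Krt8 stood at 900, 863 and 458 CPM in the 3 libraries, and Krt18 at 431, 676 and 479. With so few tumour cells left by the CD45+ sort, these values were not tested between groups.

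**Figure D1:**
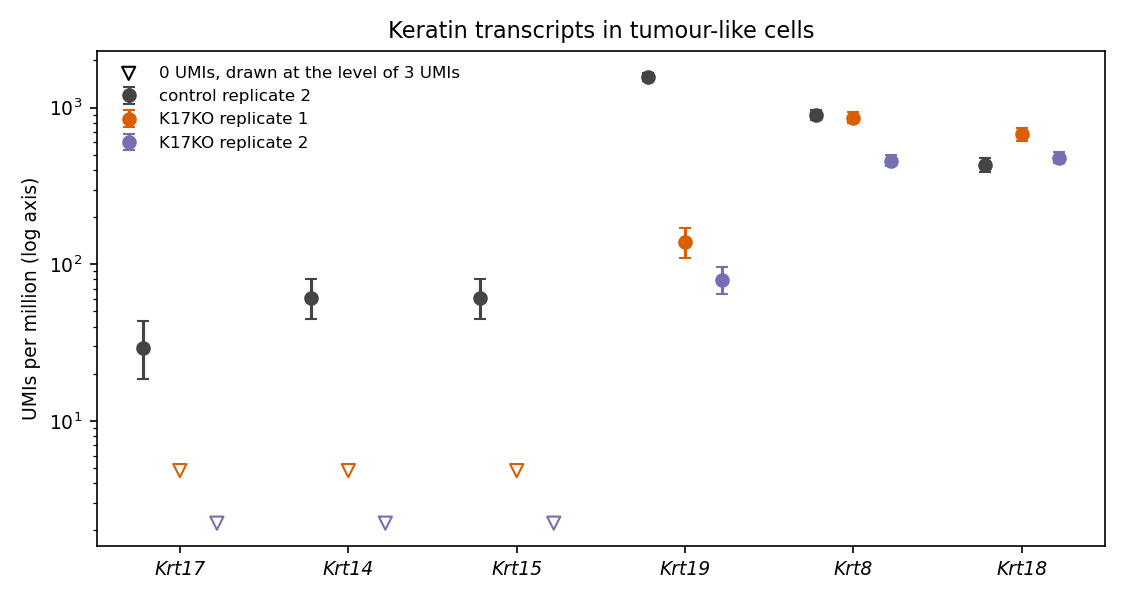
CPM (log axis) of 6 keratin genes in the tumour-like cells of control replicate 2, K17KO replicate 1 and K17KO replicate 2. Points are values with 95% exact Poisson intervals, and open triangles stand for 0 UMIs at the level of 3 UMIs. Krt17, Krt14 and Krt15 had UMIs only in the control library.

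The mix of immune cells differed between the libraries. Neutrophils made up 59.1% of the control cells (95% exact binomial interval 57.9 to 60.4) against 26.4% (25.1 to 27.8) and 18.6% (17.4 to 19.9) in the K17KO libraries. Their K17KO mean was 22.5% ± 5.53 (SD, n = 2), 2.63-fold below the control. NK cells stood at 1.832% (1.503 to 2.209) in the control. The K17KO mean was 8.90% ± 0.0397 (SD, n = 2), 4.86-fold above it. T cells stood at 6.42% (5.80 to 7.08) against 18.8% ± 1.96 (SD, n = 2), 2.93-fold above the control, and dendritic cells at 2.55% against 4.93% ± 0.479 (SD, n = 2). Monocytes and macrophages were at 20.4% and 22.96% ± 0.451 (SD, n = 2). B cells (0.531%, 0.952% and 0.444%), basophils (0.205%, 0.511% and 0.496%), mast cells (0.342%, 0.116% and 0.183%) and plasmacytoid dendritic cells (0.0856%, 0.232% and 0.0783%) were rare in all 3 libraries.

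No class passed the threshold of 0.05 after adjustment over the classes (edgeR). The adjusted p was 0.0560 for NK cells, 0.0726 for T cells, 0.124 for neutrophils, 0.113 for dendritic cells and 0.450 for monocytes and macrophages. The exact permutation test of 1 library against 2 cannot give a p below 0.333. Cells had been sorted as live and CD45+ before capture, and 7.96%, 13.6% and 24.8% of the cells of the 3 libraries sat in clusters left unnamed. Among these, cluster 1 matched T cells best (4 of 15 markers) and held 0.034%, 10.7% and 22.8% of the cells. The T cell share and its fold over the control therefore depend on leaving this cluster unnamed. The NK cell share passed under 9 alternative settings and the T cell share under 3. Of the cells outside neutrophils, T cells made up 15.7% in the control against 27.4% and 21.4%, NK cells 4.48% against 12.1% and 10.97%, and dendritic cells 6.24% against 7.17% and 5.65%. Monocytes and macrophages, at 49.9% against 31.6% and 27.8% of these cells, turned lower, as they did under 2 other alternatives, and no class passed on this scale either.

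**Figure D2:**
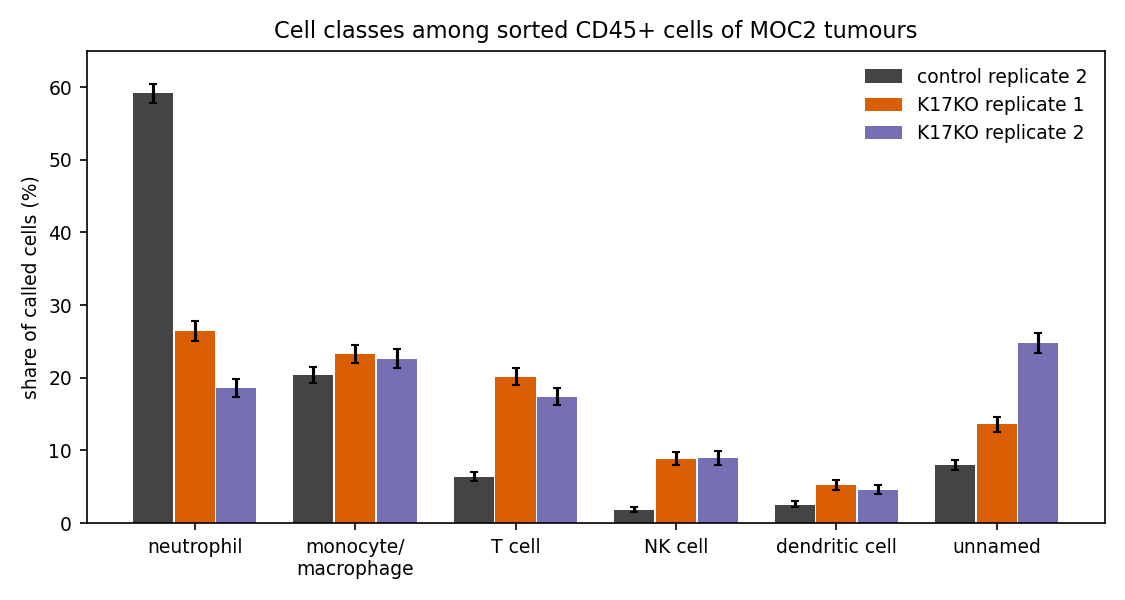
Share of called cells (percent) in 5 immune classes and in unnamed clusters, for control replicate 2, K17KO replicate 1 and K17KO replicate 2. Bars are shares with 95% exact binomial intervals. Neutrophils take 59.1% of the control bar against 26.4% and 18.6%, and no class passed the test between groups.

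With all CD45+ cells of a library summed, transcripts of cytotoxic lymphocytes rose in K17KO tumours. Gzma, a granzyme of killer cells, rose by 3.18 ± 0.29 (log2 ± SE; 73.6, 882 and 658 CPM in the 3 libraries; adjusted p = 0.0102, edgeR). Ifng, the gene of interferon-gamma, rose by 2.28 ± 0.19 (18.4, 96.0 and 110 CPM, adjusted p = 0.00904), Pdcd1, the gene of the checkpoint receptor PD-1, by 1.80 ± 0.21 (adjusted p = 0.0120) and Cd8a, the marker of CD8 T cells, by 1.58 ± 0.22 (adjusted p = 0.0159). Of 16 measured cytotoxic effector genes 13 rose and 0 fell (13 rose and 2 fell, adjusted over the list alone, camera adjusted p = 5.97e-07; adjusted p = 0.581 with an estimated correlation). Killer-cell receptor genes outside the lists rose with them, Klrc2 by 2.04 ± 0.21 and Klre1 by 1.82 ± 0.20, and so did Thy1 and Zap70, which serve T cell signalling.

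Inflammatory cytokine genes and tissue macrophage genes were lower in the same sums. Il1b, the gene of interleukin-1 beta, changed by -1.78 ± 0.20 (log2; 11870, 4307 and 3688 CPM, adjusted p = 0.0118, edgeR), Osm by -1.69 ± 0.20 and Cxcl1, a neutrophil chemokine, by -1.65 ± 0.16. In the inflammatory cytokine list 9 of 17 genes fell (12 adjusted over the list alone), and in the complement and tissue macrophage list 8 of 16 fell (15 adjusted over the list alone), among them Trem2 at -2.10 ± 0.15 and Ms4a7 at -2.32 ± 0.19. Of 18 suppressive myeloid genes 8 fell, among them the angiogenesis inhibitor Thbs1 at -2.52 ± 0.20, and 1 rose (8 and 1 adjusted over the list alone). In the hypoxia and glycolysis list 5 of 20 fell (10 adjusted over the list alone), among them the glucose transporter gene Slc2a1 at -1.44 ± 0.20. Monocyte genes went both ways (2 rose and 3 fell of 12, 2 and 5 adjusted over the list alone, camera adjusted p = 0.406), with Ly6c2, a marker of inflammatory monocytes, higher by 1.76 ± 0.22 (155, 643 and 568 CPM, adjusted p = 0.0134). Outside the lists Pf4 changed by -4.08 ± 0.42 and Lrg1, a neutrophil granule gene, by -3.23 ± 0.18. Each of the lower lists passed camera, with an adjusted p of 4.04e-07 for complement, 6.07e-06 for inflammatory and for hypoxia genes and 0.00216 for suppressive genes (adjusted p = 0.581 with an estimated correlation, each).

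Interferon-induced genes were also higher in the sums, with 5 of 22 interferon-gamma-induced genes risen (14 adjusted over the list alone, camera adjusted p = 6.07e-06; adjusted p = 0.581 with an estimated correlation). Cxcl10, a chemokine that draws T cells, rose by 1.44 ± 0.29 (206, 531 and 762 CPM, adjusted p = 0.0428, edgeR), whereas Cxcl9 stood at 1.65 ± 0.76 (adjusted p = 0.299) and did not pass. The type I interferon list (3 of 23 rose, 8 adjusted over the list alone, camera adjusted p = 0.000399) and MHC class I presentation (2 of 16 rose, 3 adjusted over the list alone, 1.61e-05) also passed. Each of them had adjusted p = 0.581 with an estimated correlation. Smaller counts came from cell cycle genes (1 of 20 rose, 1 adjusted over the list alone, 6.07e-06), regulatory T cell genes (2 of 11 rose, 6 rose and 1 fell when adjusted over the list alone, 0.00304) and checkpoint genes (4 rose and 1 fell of 13, 6 and 2 adjusted over the list alone, 0.0123). Immediate early genes (4 of 20 fell, 9 adjusted over the list alone) and naive and memory T cell genes (2 rose and 1 fell of 9, 5 and 2 adjusted over the list alone) each had a camera adjusted p of 0.0495. For these 5 lists too the adjusted p = 0.581 with an estimated correlation. Foxp3 (0.01 ± 0.17), Cd274 (-0.12 ± 0.20), Cd4 (1.26 ± 0.57) and Arg1 (-1.94 ± 1.23; 1533, 781 and 147 CPM) did not pass.

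In all, 1258 of 15117 genes passed in the summed cells, 418 higher and 840 lower in K17KO (edgeR), in libraries whose class shares differ as given above. The split depends on the scaling: with library size only, 741 were higher and 568 lower, and the median of all genes then lay at 0.22 (log2). Tested without a gene filter, 0 of 21507 genes passed with edgeR, 3786 had an unadjusted p under 0.05, and DESeq2 with the filter called 1629.

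Within neutrophils, interferon-induced genes rose in K17KO tumours. Gbp4, a guanylate-binding protein gene induced by interferon-gamma, rose by 4.32 ± 0.29 (log2 ± SE; 3.72, 68.1 and 83.1 CPM, adjusted p = 2.29e-45, edgeR), Cxcl10 by 2.96 ± 0.34 (194, 1406 and 1635 CPM) and Cxcl9 by 2.74 ± 0.26 (20.9, 160 and 125 CPM). Cd274, the gene of the checkpoint ligand PD-L1, rose by 1.25 ± 0.31 (617, 1520 and 1456 CPM, adjusted p = 0.00141). Of the interferon-gamma-induced genes 20 of 21 rose (20 adjusted over the list alone, camera adjusted p = 4.60e-23). Of the type I interferon-induced genes 22 of 22 rose (22 adjusted over the list alone, 1.91e-20), among them the antiviral gene Ifit2 by 2.92 ± 0.26 and the nucleic acid sensor Zbp1 by 2.37 ± 0.28. Both lists had adjusted p = 0.683 with an estimated correlation.

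Antigen presentation genes rose beside them. In the MHC class I list 15 of 16 rose (16 adjusted over the list alone, camera adjusted p = 1.72e-16; adjusted p = 0.683 with an estimated correlation), among them the transactivator Nlrc5 by 1.99 ± 0.25, the immunoproteasome subunit Psmb10 by 1.76 ± 0.25 and H2-Q7, which has close paralogs, by 2.44 ± 0.25. At the upper limit of free RNA given next, H2-Q7 would owe it 64.7% and 48.6% of its K17KO level. In the MHC class II list 3 of 8 rose (7 adjusted over the list alone, 0.000155) and in the cytotoxic list 7 of 14 rose (12 adjusted over the list alone, 1.06e-11), both with adjusted p = 0.683 with an estimated correlation. An upper limit on free RNA, from C1q and Apoe transcripts, was 2.73%, 7.84% and 5.52% of the neutrophil UMIs of the 3 libraries. At these limits free RNA would give 135% and 192% (MHC class II) and 445% and 188% (cytotoxic) of the median called gene's level in the K17KO libraries. Shares over 100% show that the limits lie too high, so how much of these 2 lists is free RNA stays open.

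Genes that fell in neutrophils included Mmp19, a matrix metalloprotease gene (-2.08 ± 0.22), Entpd3 (-1.69 ± 0.22), Snai1 (-1.54 ± 0.22), the leukotriene receptor gene Cysltr1 (-1.54 ± 0.22) and Lrg1 (-1.47 ± 0.27). Complement and tissue macrophage genes did not pass as a list (median -0.10, camera adjusted p = 0.561), with only Gpnmb risen, and neither did hypoxia genes (0.593), inflammatory genes (0.722), immediate early genes (0.593), suppressive genes (0.634, 5 rose and 1 fell), monocyte genes (0.593, 5 rose and 1 fell), chemokines (0.278), cell cycle genes (0.395) or the checkpoint (0.0521), regulatory (0.122) and naive T cell lists (0.311). Arg1 had a fitted change of 1.28 ± 0.24 (adjusted p = 4.08e-06, edgeR) that K17KO replicate 1 alone made, with 33.0, 134 and 30.4 CPM. Without K17KO replicate 1 the change was -0.06.

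In all, 702 of 9436 genes passed in neutrophils, 483 higher and 219 lower (edgeR), with a single spread for all genes of a like level, since the fit found no more variation between them. DESeq2 called 231 genes, 195 higher and 36 lower, and 308 passed with cells thinned to 1000 UMIs. Different clusters held most neutrophils in the groups: clusters 0 and 2 held 54.0% and 31.9% of the control neutrophils, and cluster 0 held 5.10% and 7.16% of those in the K17KO libraries. Cluster 3, led by the interferon-induced genes Rsad2, Ifit1 and Gbp5, held 48.2% and 61.8% of K17KO neutrophils against 7.44% of the control, and cluster 9, led by hypoxia genes, 26.9% and 11.7% against 2.95%.

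**Figure D3:**
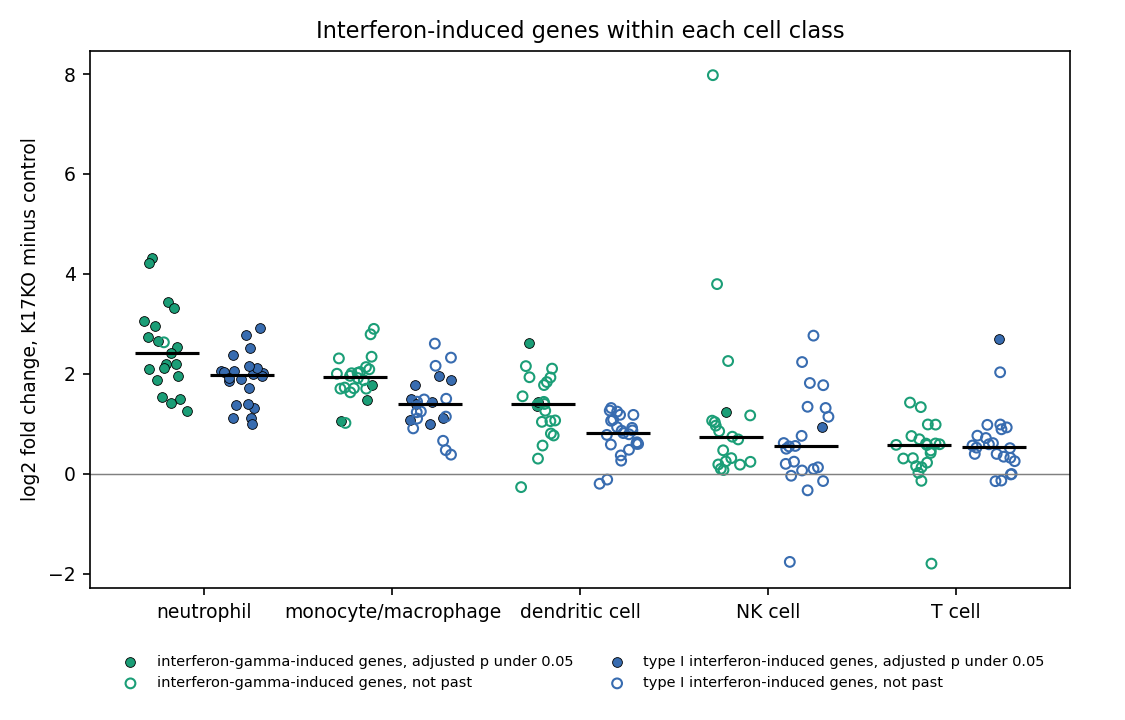
Fitted log2 fold change (K17KO minus control) of each gene of the interferon-gamma and type I interferon lists, by cell class. Each point is a gene, filled where its adjusted p lies under 0.05, and bars are list medians. In neutrophils 20 of 21 and 22 of 22 points are filled, and in T cells 0 of 21 and 1 of 22.

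Within monocytes and macrophages, some monocyte and interferon-induced genes rose and some tissue macrophage genes fell. Ly6c2 rose by 1.95 ± 0.16 (log2 ± SE; 235, 895 and 882 CPM, adjusted p = 0.0184, edgeR), Plac8 by 1.99 ± 0.16 and Ace by 2.21 ± 0.16. Irf1, a transcription factor gene induced by interferon, rose by 1.77 ± 0.23 (adjusted p = 0.0365), and Cd274 by 1.05 ± 0.17 (163, 309 and 351 CPM, adjusted p = 0.0467). Mmp9, a gelatinase gene, changed by -3.98 ± 0.16 (558, 36.6 and 32.7 CPM, adjusted p = 0.00448), the lipid receptor Trem2 by -1.66 ± 0.13 and the scavenger receptor Stab1 by -2.28 ± 0.26. Mmp9 is also a neutrophil marker used to name clusters. It was a leading gene of neutrophil cluster 2, which held 18.9% of the control cells against 2.44% and 1.67%. How much of its fall in this class comes from neutrophil transcripts was not tested.

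As lists, type I interferon genes (9 of 23 rose, 21 adjusted over the list alone, camera adjusted p = 1.89e-13), interferon-gamma-induced genes (3 of 22, 11 adjusted over the list alone, 1.07e-11) and MHC class I presentation (2 of 16, 12 adjusted over the list alone, 5.86e-07) were higher. Complement and tissue macrophage genes were lower (4 of 16 fell, 8 adjusted over the list alone, 4.96e-07), as were hypoxia and glycolysis genes (2 of 20 fell, 4 adjusted over the list alone, 0.000843), the members being Gapdh (-0.97 ± 0.13) and Eno1 (-0.95 ± 0.15). The monocyte list (2 of 12 rose, 5 adjusted over the list alone, 0.0376) and the naive and memory list (1 of 9 rose, 5 rose and 1 fell when adjusted over the list alone, 0.0171) were higher, the member of the latter being Klf2, a transcription factor also active in monocytes. The cytotoxic list was higher too (2 of 16 rose, 5 adjusted over the list alone, 7.31e-06), through Ccl5 and the lymphocyte gene Gzma at 0.842, 9.98 and 8.62 CPM. For each of these lists the adjusted p = 0.612 with an estimated correlation. An upper limit on free RNA, from S100a8 and S100a9 transcripts, was 8.64%, 21.7% and 11.8% of the UMIs of this class. Gzma stood at 104, 831 and 675 CPM in droplets of 1 to 100 UMIs, far above its level in these cells, so free RNA lies well below these limits.

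Cxcl9 (2.09 ± 0.86; 266, 622 and 1590 CPM, adjusted p = 0.386, edgeR), Cxcl10 (2.01 ± 0.40; adjusted p = 0.118), B2m (0.77 ± 0.13; adjusted p = 0.0505) and Arg1 (-1.39 ± 1.51; 3585, 2300 and 388 CPM, adjusted p = 0.711) did not pass in this class. The suppressive list (camera adjusted p = 0.102), in which Trem2 and Thbs1 fell, MHC class II genes (0.102), inflammatory genes (0.563), chemokines (0.572), cell cycle genes (0.107), immediate early genes (0.102), checkpoint genes (0.416) and regulatory T cell genes (0.158) did not pass either.

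In all, 306 of 11804 genes passed, 182 higher and 124 lower (edgeR). With upper-quartile scaling 124 were higher and 152 lower, with a median of all genes at -0.105 (log2), and with DESeq2 71.4% of 469 calls were higher. Without a gene filter 0 of 17847 genes passed with edgeR, with 2121 at an unadjusted p under 0.05, and Cd274 in this class did not pass with library size only or upper-quartile scaling either. The class was made of different clusters: cluster 5, led by Mmp12 and Arg1, held 47.4% of the control cells against 34.3% and 8.77% in the K17KO libraries, and cluster 4, led by Vcan and Cxcl9, 34.2% against 25.7% and 52.4%. Cluster 8, led by Ace and Hpgd, held 8.91% against 29.2% and 28.3%.

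Within T cells a granzyme gene and an interferon-induced gene rose and the regulatory T cell gene Foxp3 fell. Gzma rose by 1.86 ± 0.28 (log2 ± SE; 59.5, 206 and 218 CPM, adjusted p = 0.0176, edgeR), the interferon-induced Ifit3 by 2.69 ± 0.42 (2.77, 14.97 and 20.2 CPM, adjusted p = 0.0199), and Foxp3, the regulator of regulatory T cells, changed by -1.39 ± 0.23 (126, 50.6 and 44.0 CPM, adjusted p = 0.0256). The effector cytokine gene Ifng (0.71 ± 0.28, adjusted p = 0.594), Pdcd1 (0.29 ± 0.27), Cd8a (0.06 ± 0.27), Cd4 (-0.23 ± 0.50) and Cd274 (0.22 ± 0.24) did not pass. The regulatory T cell list was lower (1 of 10 fell, 7 adjusted over the list alone, camera adjusted p = 0.000225). Higher were the lists of type I interferon genes (1 of 22 rose, 1 adjusted over the list alone, 6.51e-06), cytotoxic genes (1 of 16, 1 adjusted over the list alone, 0.0111), interferon-gamma-induced genes (0 of 21 passed, 1 rose and 1 fell when adjusted over the list alone, 0.000201) and cell cycle genes (0 of 20 passed, 0 adjusted over the list alone, 2.56e-05). For these lists the adjusted p = 0.597 with an estimated correlation, and the checkpoint list did not pass (0.962).

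Myeloid genes were among those that fell in this class, such as Mrc1, a macrophage mannose receptor (-2.55 ± 0.24; 98.6, 18.3 and 14.8 CPM), Tgfbi (-2.12 ± 0.25), Ccl6 (-2.16 ± 0.23) and Il1b (-1.65 ± 0.28). Complement genes (3 of 16 fell, 7 adjusted over the list alone, camera adjusted p = 3.76e-07) were lower. So were inflammatory genes (4 of 17, 9 adjusted over the list alone, 1.50e-06), suppressive myeloid genes (3 of 18, 6 adjusted over the list alone, 1.52e-05), chemokines (2 of 11, 4 adjusted over the list alone, 0.0106) and MHC class II genes (0 of 11, 6 adjusted over the list alone, 0.00129), each with adjusted p = 0.597 with an estimated correlation. Chemokines turned higher with thinned cells and at resolution 2.0, and MHC class II genes with cells of at least 1000 UMIs and with OrdMag cell calling, without passing. Hypoxia and glycolysis genes were lower with 0 of 19 passed and 0 adjusted over the list alone (0.0147; adjusted p = 0.690 with an estimated correlation). In the control T cells 38 of 375 cells held 86.8% of the 18615 UMIs of the 72 lower genes other than Foxp3. An upper limit on free RNA, from S100a8 and S100a9 transcripts, was 3.72%, 5.54% and 7.24% of the T cell UMIs.

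In all, 81 of 12193 genes passed in T cells, 8 higher and 73 lower (edgeR). These sums leave out unnamed cluster 1, which matched T cells best and held 2 control cells against 461 and 872 K17KO cells. Gzmd, a leading gene of that cluster, was among the lower genes (-2.78). The T cell gene and list results therefore hold for the named T cells only. The split was 15 higher and 20 lower with thinned cells (13 calls shared), 10 and 18 at resolution 2.0 (19 shared) and 3 and 5 with up to 20% mitochondrial UMIs (6 shared). With the same test without its robust option 0 genes passed, 726 had an unadjusted p under 0.05, and DESeq2 called 56. With K17KO replicate 2 taken as the lone library in place of the control, 0 genes passed (edgeR) and 1434 had an unadjusted p under 0.05, against 816. With cells of at least 1000 UMIs 2 genes passed, and Gzma, Ifit3 and Foxp3 did not. Cluster 7, led by Cd8a, held 30.1%, 41.4% and 27.2% of the T cells, cluster 16, led by Il2ra and Foxp3, 24.8%, 12.9% and 12.6%, cluster 12, led by Cd4, 24.5%, 21.2% and 12.0%, cluster 10, led by Tcf7, 14.7%, 18.0% and 33.8%, and the cycling cluster 18 5.87%, 6.57% and 14.4%. Of all called cells, cluster 16 held 1.59%, 2.60% and 2.19%, so the fall of Foxp3 is relative to the other T cells. Gzma is also an NK cell marker, and cluster 10 had NK cells as its next match (5 markers). Whether the rise of Gzma follows these shares was not tested.

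In dendritic cells hypoxia and glycolysis genes fell together, 9 of 19 measured (11 adjusted over the list alone, camera adjusted p = 2.93e-09; adjusted p = 0.525 with an estimated correlation). Il1r2, a decoy receptor of interleukin-1, changed by -2.64 ± 0.22 (1047, 151 and 201 CPM, adjusted p = 0.000230, edgeR), the lectin gene Clec4n by -1.88 ± 0.21 and Cysltr1 by -1.84 ± 0.20. Il1r2 is also a neutrophil marker used to name clusters, and how much of its fall comes from neutrophil transcripts was not tested. Interferon-gamma-induced genes were higher (3 of 22 rose, 9 adjusted over the list alone, 1.03e-08; adjusted p = 0.531 with an estimated correlation), as were type I interferon genes (0 of 23 passed, 15 adjusted over the list alone, 8.25e-08; adjusted p = 0.525 with an estimated correlation), and MHC class II genes were lower (1 of 11 fell, 6 adjusted over the list alone, 0.000202; adjusted p = 0.531 with an estimated correlation). The T cell receptor complex genes Cd3d, Cd3e and Cd3g rose by 3.19 ± 0.41, 3.34 ± 0.47 and 3.43 ± 0.48, and the cytotoxic list rose with them (5 of 16, 7 adjusted over the list alone, 1.03e-08; adjusted p = 0.525 with an estimated correlation). Also higher were the lists of naive and memory T cell genes (1 of 9 rose, 2 adjusted over the list alone, 0.00218), monocyte genes (3 of 12, 3 adjusted over the list alone, 0.00830), chemokines (1 of 11, 1 adjusted over the list alone, 0.00698), immediate early genes (1 of 20, 3 rose and 1 fell when adjusted over the list alone, 0.00109) and MHC class I presentation (0 of 16 passed, 0 adjusted over the list alone, 0.0178), each with adjusted p = 0.525 with an estimated correlation. The checkpoint list was higher as well (2 of 12, 3 adjusted over the list alone, 0.0150; adjusted p = 0.552 with an estimated correlation). In all, 211 of 10374 genes passed, 95 higher and 116 lower (edgeR). DESeq2 called 101, 60.4% of them higher, and without the 5% of cells with the highest doublet scores 45 passed and the 3 Cd3 genes did not. The Cd3 genes are T cell markers, so their rise is not read as dendritic cell expression. How much of the cytotoxic, naive T cell and checkpoint list changes comes from lymphocyte transcripts was not tested. An upper limit on free RNA, from S100a8 and S100a9 transcripts, was 3.86%, 4.99% and 1.34% of the UMIs of this class in the 3 libraries.

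In NK cells 70 of 10213 genes passed, 21 higher and 49 lower (edgeR). Egr3, an early response gene downstream of activating receptors, changed by -2.60 ± 0.21 (126, 19.7 and 21.5 CPM, adjusted p = 4.39e-24), the oxysterol receptor Gpr183 by -1.07 ± 0.20, and the interleukin-10 receptor gene Il10ra rose by 0.98 ± 0.24. The neutrophil gene S100a8 changed by -3.96 ± 0.22 (188, 15.7 and 7.92 CPM), against 6749, 1284 and 1996 CPM in droplets of 1 to 100 UMIs. The upper limit on free RNA in NK cells, from S100a8 and S100a9 themselves, was 2.60%, 1.65% and 0.512%, so its change is not read as NK cell expression. Interferon-gamma-induced genes (1 of 19 rose, 7 adjusted over the list alone, camera adjusted p = 9.91e-05) and type I interferon genes (1 of 22 rose, 5 rose and 1 fell when adjusted over the list alone, 0.000571) were higher, both with adjusted p = 0.805 with an estimated correlation, and cytotoxic genes did not pass (4 rose and 1 fell of 16, 5 and 1 adjusted over the list alone, 0.0580). With K17KO replicate 2 taken as the lone library in place of the control, 56 genes passed, and DESeq2 called 13, without Gpr183 and Il10ra. The control held 107 NK cells.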

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

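Tests of macrophages and of depth for the neutrophil genes, and the removal of the highest doublet scores for the T cell genes, were chosen only after the result was seen. The macrophage test replaced an earlier test on complement and tissue macrophage genes (median change -0.10 in neutrophils), which was weak because these genes were also lower in K17KO monocytes and macrophages (-0.99). Its limits of 10% and 100% were set after its own values were known, so it is a description and not a prediction that held.

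The group difference of Arg1, an arginase made by suppressive myeloid cells, was itself different in neutrophils and in monocytes and macrophages, which is why it is listed. The K17KO effect in neutrophils minus that in monocytes and macrophages was 2.80 (log2, adjusted p = 2.95e-06, edgeR interaction term, library as block, 300 of 7796 genes passed). K17KO replicate 1 alone made the neutrophil change, which was -0.06 without that library. In the same test Cxcl10 (1.005, adjusted p = 0.0511), Cxcl9 (0.84, adjusted p = 0.827) and Cd274 (0.22, adjusted p = 0.794) did not pass, so their rise in neutrophils is not shown to differ from that in macrophages. The cause was not tested.

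A pair of unnamed clusters, compared with the control by no test of their own, stood above the control in both K17KO libraries. Cluster 1, led by Gzmc, Gzmd and Gzmf, granzymes of activated killer cells, held 0.034% of the control cells against 10.7% and 22.8%, with a median of 1238 UMIs per cell and 7.76% mitochondrial UMIs. The low-UMI unnamed cluster closest to T cells held 5.77% and 17.1% of the K17KO cells at a minimum of 1000 UMIs, and with OrdMag cell calling an unnamed cluster near T cells held 1.69% and 5.09%, so its size depends on how many low-UMI barcodes are kept. Cluster 15, also of low UMI count and led by Pf4, Apoe and mitochondrial genes, went the other way, with 5.02% of the control cells against 0.139% and 0.052%. Cluster 24, led by Gzmg, Gzmf, Gzmd and Gzme, held 0.034% against 0.209% and 0.757%, with a median of 11969 UMIs and 0.11% mitochondrial UMIs. Their cells are part of the summed CD45+ cells, and the unnamed clusters together did not pass as a share (adjusted p = 0.268, edgeR).

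Interferon-induced genes were higher in K17KO neutrophils, 42 members of the lists in all. At the upper limit of its share, free RNA would give a median of 2.88% of their K17KO level in the higher library and 2.102% in the other, far too little to make the change, although for Serpina3g (488% and 122%), Gbp6 (123% and 33.9%) and Iigp1 (32.3% and 73.1%) it stays open. At the mean level of monocytes and macrophages in the same library, the median member would need 139% and 130% of such cells, and more than 100% for 24 and 25 of the 42, which argues against these cells counted as neutrophils unless they are richer in interferon-induced genes than their class. With cells thinned to 1000 UMIs, 37 of the 42 were still called and their median went from 2.06 to 1.95, which argues against depth. An effect of tumour K17 on interferon signalling may explain the pattern but stays an untested hypothesis. With 1 control library, genotype cannot be separated from the tumour sampled, and more control tumours would be needed to test it. Even these would not separate K17 loss from other genome differences of the K17KO cells, a possibility raised below.

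In K17KO T cells 72 genes other than Foxp3 fell, among them myeloid genes such as Csf1r, lymphocyte genes such as Itgae and genes of neither kind such as Cav1 and Vcam1 (named after their values were seen). At the upper limit of its share, free RNA would give a median of 16.3% of their control level, and at least 50% for only 7 of them. The 10% of control T cells with most of these UMIs held 86.8% of them against 27.7% if spread by depth (highest draw 28.6%), and for the 7 genes 83.3% against 28.1%, which argues against free RNA because that spreads over cells. T cells joined to other cells in the same droplet may explain this concentration. Without the 5% of cells with the highest doublet scores 81 genes still fell in T cells (of 88 calls, 55 shared with those of the chosen settings). Because the doublet caller hardly worked on these libraries, its scores cannot decide this. Joined cells, like a biological difference in a few T cells, therefore stay open.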

How the results depend on the processing

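Removing the 5% of cells with the highest doublet scores and using named cells only were chosen after seeing the data. Of 164 named gene results past the threshold, 31 kept direction and side of the threshold under every alternative that gave a value and 6 turned sign under at least 1. Without a gene filter 114 of the 164 lost their call. Where no cause is given below, the cause was not tested. No paired analysis was possible because only replicate number 2 is shared by both groups, which leaves 1 pair.

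Krt17 had UMIs in the control alone under every setting that called cells anew or thinned them; leaving out a K17KO library cannot move the control level of 0.899 CPM. Cell class composition had 0 classes past the threshold with the chosen settings (edgeR). It had 1 at resolution 0.5, 1 at resolution 2.0, 1 with mitochondrial at most 20%, 1 with no doublet removal and 1 without the 5% highest doublet scores. It had 2 at a minimum of 1000 UMIs, 2 with mitochondrial at most 5%, 3 with OrdMag cell calling and 4 with named cells only.

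The share of NK cells among CD45+ cells (a difference of 7.07 percentage points) passed under 9 alternatives, at 7.07 with resolution 0.5 (adjusted p = 0.0414), 7.025 with resolution 2.0, 7.695 at 1000 UMIs, 9.393 with OrdMag, 9.591 and 7.006 at 5% and 20% mitochondrial, 7.005 with no doublet removal, 7.239 without the highest doublet scores and 9.083 in named cells. Over its alternatives the adjusted p ran from 0.00504 to 0.333. The share of T cells among CD45+ cells (12.36) passed with OrdMag (16.65), mitochondrial at most 5% (10.1) and named cells only (16.26). The share of neutrophils among CD45+ cells (-36.64) passed with OrdMag (-32.61), and the share of dendritic cells among CD45+ cells (2.384) with named cells only (3.336). The share of monocyte/macrophages among CD45+ cells (2.586) turned sign with OrdMag (-1.132), as a share of cells outside neutrophils (-20.14) and with TMM over classes (2.586, with a log2 ratio of -0.21); none of these passed. Leaving out 1 K17KO library gave 10.97 to 13.74 for T cells, 2.267 to 2.906 for monocytes and macrophages, -40.55 to -32.73 for neutrophils, 7.042 to 7.098 for NK cells and 2.045 to 2.722 for dendritic cells.

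Genes differing in all CD45+ cells summed went from 1258 to 0 with no gene filter (edgeR, 3786 at an unadjusted p under 0.05; DESeq2 with the filter 1629). Genes differing in NK cells (70) were 117 with library size only, 118 with no gene filter, 111 without the robust option, 13 with DESeq2, 10 with thinned cells, 106 at 1000 UMIs and 40 at resolution 2.0. Genes differing in T cells (81) were 35 with library size only, 39 at a mean CPM of 10, 35 with thinned cells, 2 at 1000 UMIs, 8 and 39 at 20% and 5% mitochondrial, 41 with OrdMag and 28 at resolution 2.0. They were 0 with no gene filter (edgeR, 544 at an unadjusted p under 0.05) and 0 without the robust option (726), against 56 with DESeq2.

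Genes differing in dendritic cells (211) were 115 with library size only, 576 with no gene filter, 101 at a mean CPM of 10, 98 without the robust option, 101 with DESeq2, 43 with thinned cells, 445 and 58 at 20% and 5% mitochondrial, 473 with no doublet removal, 503 with OrdMag and 45 without the highest doublet scores. Genes differing in monocyte/macrophages (306) were 181 with library size only, 0 with no gene filter (edgeR, 2121 at an unadjusted p under 0.05), 191 at a mean CPM of 10, 469 with DESeq2, 640 at 1000 UMIs, 618 at 5% mitochondrial, 491 with no doublet removal and 162 without the highest doublet scores. Genes differing in neutrophils (702) were 231 with DESeq2 (228 shared) and 308 with thinned cells (299 shared).

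Of 50 gene list tests that passed with camera, 0 passed with an estimated correlation and 0 with fry, checks that could hardly pass with 1 residual degree of freedom. In T cells chemokines attracting monocytes and lymphocytes turned to 0.47 with thinned cells and 0.75 at resolution 2.0, and MHC class II presentation to 0.28 at 1000 UMIs and 0.31 with OrdMag. In T cells Ccl8 turned to 2.16 at 5% mitochondrial, Il6 to 2.35 at 20%, and Fn1 to 0.17 at 20% and 1.32 at 5%. Gadd45b in NK cells turned to -0.48 with thinned cells. In neutrophils Arg1 ran from -0.06 to 1.91 and Retnla from -0.95 to 3.07 as 1 K17KO library was left out, with the lower values without K17KO replicate 1, the library that made their rise. Depth limits what can be tested, since with thinned cells 3539 genes could be tested in dendritic cells against 10374, and 5530 in NK cells against 10213.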

Other observations

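Every test of the tumour-like cells was chosen only after the result was seen.

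UMIs of T cell chemokines were found in tumour-like cells, mostly in the K17KO libraries. Cxcl10 had 6, 399 and 448 UMIs in control replicate 2, K17KO replicate 1 and K17KO replicate 2 (7.58, 640 and 332 CPM), in 2 of 33, 7 of 25 and 18 of 71 cells. Cxcl9 had 2, 224 and 173 UMIs (2.53 CPM in the control, exact Poisson interval 0.306 to 9.13, then 359 and 128), in 1, 3 and 14 cells. The interferon-induced genes Gbp2 (75.8, 573 and 1731 CPM) and Iigp1 (129, 390 and 2317 CPM) were higher in both K17KO libraries too. Few cells made these sums, with 273 of the 399 Cxcl10 UMIs of K17KO replicate 1 in 1 cell, and the values were not tested between groups. Droplets of 1 to 100 UMIs held Cxcl10 at 184, 460 and 823 CPM, Cxcl9 at 108, 178 and 542, Gbp2 at 372, 644 and 1016 and Iigp1 at 28.9, 63.5 and 184. The neutrophil gene S100a8 stood at 6749, 1284 and 1996 CPM in those droplets against 32.9, 135 and 40.03 in the tumour-like cells. Free RNA is therefore a small part of these cells and cannot make most of the chemokine counts in the K17KO libraries, but joined immune cells were not tested, so whether tumour-like cells express these genes stays open. All these genes were named after their values were seen.

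Other genes had lower counts in the K17KO tumour-like cells than in the control. Xist, the RNA that silences an X chromosome, had 261, 0 and 0 UMIs, all in 5 control cells, and the matrix gene Mgp 3251, 0 and 16, with 2192 of the 3251 in 1 of the 6 control cells that had any. Krt7 stood at 986, 132 and 185 CPM and the adhesion gene Cdh1 at 97.3, 3.21 and 2.97. The Y-linked Ddx3y had few UMIs in the tumour-like cells of every library, with 7, 1 and 5 (8.848, 1.605 and 3.706 CPM). Over all called cells it stood at 153.9, 140.9 and 114.6 CPM and was found in 3028, 2074 and 1726 cells of the 3 libraries.

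Krt14, Krt15 and Xist were missing from K17KO tumour-like cells. Of 13 control cells with at least 20000 UMIs, 6 held a Krt14 UMI, 5 a Xist UMI and 3 a Krt15 UMI. At this share 16.6 of the 36 K17KO cells of that depth were expected to hold a Krt14 UMI, 13.8 a Xist UMI and 8.31 a Krt15 UMI, and 0 did. This argues against too few cells for Krt14 and Xist only if the share in 1 control library holds for other tumours, and leaves it open for Krt15. Krt19, between Krt15 and Krt17 on chromosome 11, kept 86 and 107 UMIs, which argues against a single deletion from Krt15 to Krt17 on every copy. Neighbouring genes on chromosome 17 (63057452 to 66519729, mm10) were shifted together by a median of 1.45 and 1.68 (log2) in K17KO replicates 1 and 2. The most in 1000 shuffles was 0.87. Another block on chromosome 17 was shifted by 1.04 and 1.08. On chromosome 8, 2 blocks were shifted by -1.40 and -1.39 and by -1.26 and -1.46, against -1.18 in the shuffles. The same blocks lay between -0.13 and -0.01 in T cells and between -0.11 and 0.10 in monocytes and macrophages. K17KO cells may therefore descend from a clone with another genome. That is a hypothesis, and an effect of K17 loss on these genes stays open and untested.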
